A study of Mus musculus with 2 samples.

How the data were processed

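The data are aligned reads from LRH-1 chromatin immunoprecipitation followed by sequencing (ChIP-seq) and from input, 1 library each, from pancreas of male mice. Per the labels, the antibody came from R&D Systems, libraries were amplified and read on an Illumina/Solexa Genome Analyzer, and the background strain was ROSA26 Tam-ERCre. The labels' growth protocol describes adult males with floxed Lrh1 alleles, with or without the tamoxifen-inducible recombinase, given tamoxifen before sacrifice; it does not say which of these gave the chromatin. Groups were taken from the sample titles.

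Per the submitters' processing notes, reads were aligned with Bowtie to mm9; the Bowtie version and its settings are not given in the sources used here. Per the deposited files, each line is 1 aligned read of 36 bases with its strand, leftmost position counted from 0, bases and mismatches, in Bowtie's default layout. The deposited lines show at most 2 mismatches per read and 0 other placements for every read. No duplicate removal, peak calling or pooling was visible in them. The share of reads without a mismatch was 91.1% in the input and 90.0% in the LRH-1 ChIP. The input file names 8 unplaced contigs beside the chromosomes and the LRH-1 file names none, so the references or filters of both files differed. Each file belongs to 1 sample, and 0 columns were left without a sample.

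Everything from here on was computed from those lines with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib. Chromosomes 1 to 19, X and Y were used. Of reads with the same start and strand 1 was kept, which removed 0.811% of the input reads and 14.1% of the LRH-1 reads. In the LRH-1 library 21.6% of reads inside the regions and 12.8% outside were such repeats, so that reads of separate molecules stacked at strong sites can be lost with PCR copies. Keeping every read was tried as an alternative. The fragment length was the distance of the strand cross-correlation maximum above 60 bp, and each read was moved to the middle of a fragment of the LRH-1 length.

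Regions were called with a local Poisson model of the MACS type. LRH-1 reads in windows of 200 bp, stepped by 50 bp, were compared with the largest of the scaled input over the genome (0.843 reads per window), the window itself and the surrounding 1, 5 and 10 kb. Input was scaled by 1.03, the ratio of reads kept. Windows with a Benjamini-Hochberg adjusted p of at most 0.01 over 52836482 windows and at least 4 times the expected reads were merged across gaps of up to 200 bp. The largest p called was 3.0e-05, and a called window held at least 7 LRH-1 reads and a median of 21. The fold of a region is that of its strongest window, with an exact Poisson interval of the ChIP count. The summit is the highest point of the pileup of reads extended to the fragment length. A region whose surroundings (within 5 kb) held at least 10 LRH-1 reads outside regions and at least 4 times the scaled input was marked as lacking input: 136 regions, 38 of them on Y.

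The caller was tested on simulated reads from chromosome 19 with 50 sites at each strength: it called 12.0% of sites at 4 times background, 58.0% at 8 times, 98.0% at 16 times and 100% at 32 times, and 0 of the 134 regions it called lay away from a simulated site. Regions near the threshold are therefore a partial list. Both simulated libraries were Poisson draws from the same smoothed input rate, so the simulation could not show false calls that come from differences between the libraries. Sites were placed only where that rate was above its median, so the shares called do not cover sequence with little input. A random split of the LRH-1 reads into equal parts gave 21782 and 21651 regions, of which 74.3% and 74.7% overlapped a region of the other part. These parts come from 1 library and show sampling of reads, not biological spread.

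No genome sequence of mm9 was used. Reference bases were rebuilt from the reads: the bases of a read with each recorded mismatch replaced by the recorded reference base are the mm9 bases it covers. All 1064598 input and 1422697 LRH-1 mismatches checked lay in place (0 conflicts with the read). Motifs were searched on both strands within 100 bp of summits and in equal windows centred 1000 bp to either side; density ratios for other motifs used 50 bp around summits against 250 to 1000 bp away. Because a base is known only where a read lies, and LRH-1 reads pile up at regions, shares in flanks are too low and densities per known base are given instead. Neighbouring regions were not left out of the flanks, and flank bases are known partly through LRH-1 reads, which can raise motif densities there. The motif search found 200 of 200 sites planted in random sequence. Reordered motifs held no CpG and no NR5A core; 100 were used for shares and 20 for ratios. For the ratio at motif variants, copies were taken from bases under input reads alone, and reads overlapping the copy were left out. Shares of regions were compared by Fisher's exact test, two-sided, over the regions of this 1 library. Shares carry exact binomial (Clopper-Pearson) intervals, ratios the matching conditional interval, and a count of 0 an upper limit of 3 counts.

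Before the data were examined, the tests, the rule for named regions (the 10 with the highest lower bound of fold) and these alternatives were fixed: all reads kept, adjusted p at most 0.0001, at least 8 times the expected reads, input scaled on windows without enrichment (scale 0.885), no input in the expected count, 50% of LRH-1 reads, the NR5A core, 50 bp around summits, and narrow gaps. The plan also held the share of regions near transcription start sites and near genes of fixed lists, with named genes from each. The lists were digestive enzymes, acinar transcription factors, exocytosis, and folding and stress of the endoplasmic reticulum. Further lists were known LRH-1 targets, islet, duct, stromal and immune, and ribosomal protein genes, and genes of other tissues. These need gene positions on mm9, which were not used here. The gene table at hand is for the GRCm38.p6 build and gives no start sites, so no coordinate of it was set against the reads and no gene is assigned to a region. Reads on the mitochondrial genome and the unplaced contigs were left out of the comparisons.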

Results

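The series profiled where LRH-1 (gene symbol Nr5a2), a nuclear receptor of the NR5A family, sits on the genome of the mouse pancreas. Chromatin from the pancreas of male mice of the ROSA26 Tam-ERCre background was precipitated with an antibody against LRH-1 and sequenced, and a library of unprecipitated chromatin (input) was sequenced beside it. There was 1 library of each kind, so no value below has a replicate, and tests on the reads compare these 2 libraries rather than conditions. The input file held 10409389 aligned reads and the LRH-1 file 12320924. With 1 read kept per start and strand on the 19 autosomes, X and Y, 10299725 input reads and 10575925 LRH-1 reads entered the comparisons. Intervals are exact 95% intervals and cover counting error only, because there was 1 library of each kind. Reads amplified by PCR without molecular identifiers are not independent molecules, so intervals on read counts can be too narrow. All positions are on the mm9 build. Gene positions on that build were not used here, so regions are given by position and by the sequence they hold.

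The first comparison, LRH-1 ChIP against input, asked where LRH-1 was enriched. LRH-1 reads were concentrated in 31973 regions, of which 31903 lay on the autosomes and X. The other 70 lay on Y, where LRH-1 reads exceeded scaled input 6.73 times over the whole chromosome. The median region held 8.30 times the expected reads at its strongest window, where the expected number is the largest of the scaled input over the genome, the window and its surroundings, and 3375 regions reached 20 times or more and 341 reached 50 times or more. The regions had a median width of 350 bp and covered 0.497% of the genome that held reads, yet took 13.1% of the LRH-1 reads (13.107 to 13.148%) against 1.55% of the input reads (1.54 to 1.56%). The fold at the 10th percentile was 4.87 and at the 90th 20.5.

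Regions were spread over every chromosome. The autosomes held 13.2 regions per Mb of covered sequence, from 10.2 on chromosome 1 to 19.8 on chromosome 11, with 19.6 on chromosome 19, and X held 4.38. Read density on X was also low in both libraries, at 0.277 times the autosomal density in the input and 0.295 times in the LRH-1 ChIP. The expected count was never set below the genome average of the input, so windows on X had to exceed their own background by more to be called. Calling the other way round, input over LRH-1 ChIP, gave 840 regions, 2.63% of the number above. Strand cross-correlation in the LRH-1 ChIP peaked at 125 bp, at 4.12 times its level at 500 bp. In the input it was low and broad, at 1.491 times at 60 bp, 1.504 times at its maximum of 75 bp and 1.457 times at 95 bp. The input maximum therefore gives no firm fragment length, and a difference in fragment length between the libraries is not shown. The number of regions was still rising with depth: 50% of the LRH-1 reads gave 21655 regions and 75% gave 27144. Their number also depended on the rules of the call, with 17877 regions at 8 times the expected reads or more and 81733 when the input was left out of the expected count.

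The strongest single region, by the lower bound of its fold, was at chromosome 6:40994251 to 40995550. Its summit window had 184 times the expected reads (161 to 210), and the region held 349 LRH-1 reads and 10 input reads. A single NR5A site lay 17 bp from its summit, within the mm9 sequence ATTGATTCTTTCAAGGCCACTAAACCACA. Next came chromosome 8:96843401 to 96844450 at 183 times (155 to 214), where the surroundings held almost no input reads. Its fold rests on the genome average of the input, 0.843 reads per window, as do those of the regions named here on X, on chromosome 16 and on chromosome 4 from 116345251, which held 0 or 1 input reads. It carried CCAAGGCCA at 23 bp from its summit. The third, at chromosome 4:59674901 to 59675500, reached 172 times (148 to 199) with 206 LRH-1 reads and 3 input reads, and held the core AAGGYCA without the full motif. The region on chromosome 15 from 90419951 to 90420750 reached 143 times (122 to 167) and had TCAAGGTCA at 23 bp from its summit, in CGGCAGGAAATCAAGGTCACATAGCTGGA. The region on X from 9330101 to 9330700 reached 138 times (114 to 165), with TCAAGGCCA at 3 bp from its summit and a GATA site (WGATAAG) in the same 29 bases, CCTGATCAATTCAAGGCCACTGATAAGAT.

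Among the 10 strongest regions, 5 held the NR5A motif YCAAGGYCA within 100 bp of the summit and 6 held its core. The 4 without the core each held a site that differed from YCAAGGYCA by 1 base, and in each the nearest such site lay within 7 bp of the summit. These were CCGAGGTCA on chromosome 12 (37401001 to 37401500, 135 times), CCAAGGTTA on chromosome 16 (69094501 to 69095150, 135 times), CCAAGGACA on chromosome 13 (49632201 to 49632850, 128 times) and TCAAGGTCT on chromosome 4 (6165901 to 6166650, 127 times). The remaining region, on chromosome 4 from 116345251 to 116345800, reached 144 times (119 to 171), with CCAAGGCCA at 10 bp from its summit. Over all 21026 regions without the core, 37.8% held a site with 1 changed base within 100 bp.

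The second comparison asked how often LRH-1 regions carried the sequence that NR5A receptors bind as monomers. The full motif YCAAGGYCA was present within 100 bp of the summit in 6835 regions, 21.4% (20.9 to 21.8%), and the shorter core AAGGYCA in 10947, 34.2%. Reordering the bases of the motif gave a median of 0.873% of regions over 100 reordered motifs and at most 2.18%. Reordered motifs were also rarer than the motif away from summits, so they understate its background. In the 20 bp step at -1006 bp from the summits the motif had 228 per Mb and the mean of 20 reordered motifs 46.7. Motifs clustered at the summits, with 53.5% of those found lying within 20 bp and 87.8% within 50 bp. Parts of the motif led the sequence words: of all 8-base words within 50 bp of the summits, ranked by z score against the copies expected from the flanks, CAAGGTCA came first, with 3854 copies where 343 were expected, followed by GACCTTGA (2528 copies, 233 expected) and CAAGGCCA (3360 copies, 419 expected). In motifs per Mb the summits held 1253 and windows centred 1000 bp away held 201, a ratio of 6.24 (5.82 to 6.70). Only bases under a read are known here, 92.3% of 9-base words at the summits and 36.4% in the flanks, which makes flank densities less representative than those at summits. Flank bases are known partly through LRH-1 reads, and neighbouring regions were not left out of the flanks. Both can raise the motif density there, also in the step at -1006 bp. At 126 bp to the left of the summits the density was 99.1 per Mb, so the ratio depends on the flank chosen.

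**Figure D1:**
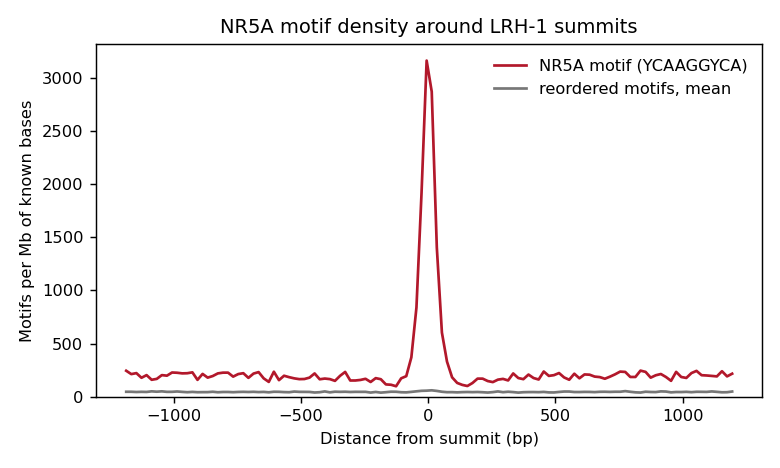
Density of the NR5A motif in motifs per Mb of known bases against distance from the LRH-1 summits in bp, in 20 bp steps over the 31973 regions, with the mean of 20 reordered motifs for comparison. The density has a sharp maximum of 3161 per Mb at the summits, with lower values beside it (99.1 per Mb at 126 bp to the left) than in windows centred 1000 bp away (201 per Mb).

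Stronger regions carried the motif more often. In the strongest decile of regions by p, with a median fold of 24.7, 32.7% (31.1 to 34.4%) held YCAAGGYCA, and 49.5% held the core. In the weakest decile, with a median fold of 6.26, 14.5% (13.3 to 15.8%) held the motif and 24.3% the core; the shares with the motif differed by Fisher's exact test (two-sided p = 3.6e-67), a test over regions of 1 library, which are not replicates. Regions with 2 or more motifs were rare, 288 or 0.901%. The weakest decile also had fewer known bases, 77.3% of 9-base words against 99.7% in the strongest. Regions in which every 9-base word was known, 17536 of them, held the motif in 22.7%.

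The third comparison measured LRH-1 enrichment around the genomic copies of each form of the motif, without calling regions. Copies of each sequence were found in the bases under input reads, and LRH-1 reads within 100 bp were divided by scaled input reads. Around all 34209 copies of YCAAGGYCA the ratio was 3.18 (3.15 to 3.22), against 1.09 (1.08 to 1.09) around 20 reordered motifs pooled, whose single ratios ran from 0.943 to 1.43. Forms with T at position 7, counted from 1 at the 5′ end of TCAAGGTCA, had the higher ratios: CCAAGGTCA (T1C) 3.56 (3.48 to 3.63) and TCAAGGTCA 3.42 (3.35 to 3.49). TCAAGGCCA (T7C) had 2.97 (2.91 to 3.03) and CCAAGGCCA 2.90 (2.84 to 2.96).

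Most single changes outside these forms lowered the ratio, by amounts that depended on the position. At G5 and G6 no change exceeded 1.25. The ratio was 1.01 (0.966 to 1.05) for G6C and 1.05 (1.01 to 1.11) for G6A, within the range of the reordered motifs, and 0.864 (0.784 to 0.953) for G5C, below that range. Changes at A3 ran from 1.08 (A3C) to 1.54 (A3G) and at A4 from 1.10 (A4C) to 1.60 (A4G). At position 2 the ratio was 1.28 for C2A, 1.403 for C2T and 1.99 for C2G, so that position overlapped with A3 and A4. At position 8 it was 1.57 for C8A, 1.63 for C8G and 2.51 (2.41 to 2.62) for C8T. At positions 1, 7 and 9 the ratio was 2.03 (1.97 to 2.09) for T1A, 1.99 for T1G, 1.79 for T7G, 2.35 (2.28 to 2.41) for T7A, 1.89 for A9C and 2.27 (2.19 to 2.35) for A9T. One change did not lower it: TCAAGGTCG (A9G) had 3.45 (3.21 to 3.72) over 575 copies, with an interval that overlaps that of TCAAGGTCA. The changes A9G, G5C, A3G and A4C each create a CpG, and these forms had the fewest copies (575, 616, 883 and 1099). The reordered motifs held no CpG, so no control matched these 4 forms. Copies of the other forms were not matched for the chromatin or sequence around them either. No ratio in this comparison can be read as base preference alone.

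**Figure D2:**
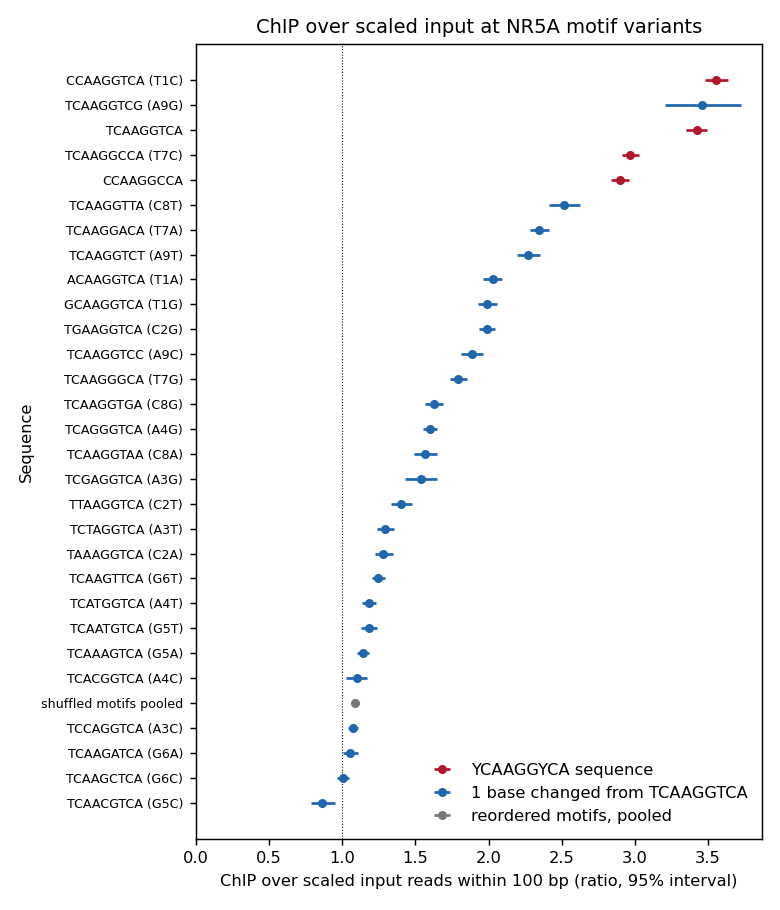
Ratio of LRH-1 ChIP to scaled input reads within 100 bp of each sequence (x axis), for the forms of YCAAGGYCA, for each single change from TCAAGGTCA and for 20 reordered (shuffled) motifs pooled; points are ratios and bars exact 95% intervals from read counts. Changes at G5 and G6 run from 0.864 to 1.25, while C8T, T7A and A9T have 2.51, 2.35 and 2.27.

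The fourth comparison asked whether LRH-1 regions also held sites of the kind bound by PTF1, the acinar complex of PTF1A, an E protein and RBPJ or RBPJL, which the title of the series names beside LRH-1. Such sites join an E-box (CASSTG) and a TC-box (TTYCCA) in a fixed orientation, spaced by whole turns of the DNA helix. LRH-1 summits showed this spacing. At a gap of 6 bp there were 201 pairs (174 to 231), against 23 (14.6 to 34.5) with the TC-box turned round, and at 16 bp there were 102 (83.2 to 124) against 38 (26.9 to 52.2). Neighbouring gaps were raised too, with 132 pairs at 5 bp (46 in the opposite orientation) and 91 at 15 bp (47). The median over gaps away from 4 to 7, 14 to 17 and 25 to 27 bp was 39 pairs, so the counts at 6 and 16 bp were 5.15 times and 2.62 times as high. These are raw counts, and fewer start positions were known at wider gaps (5273901 at 6 bp, 3878719 at 40 bp), which raises the first ratio. A smaller rise at 27 bp, 61 pairs (46.7 to 78.4) against 34 (23.5 to 47.5), had intervals that touched.

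In all, 1439 regions, 4.50% (4.28 to 4.73%), held a pair with a gap of 4 to 30 bp, against 3.04% for the opposite orientation. Within 50 bp of the summit the share was 2.64%. With the gap held to 5 to 7 or 15 to 17 bp, 630 regions or 1.97% (1.82 to 2.13%) held a pair, against 225 or 0.704% for the opposite orientation. Of these narrow pairs 43.9% used the E-box CAGCTG and 53.3% CACCTG or its reverse complement. These shares were near those among all E-boxes of the class at summits, 41.1% and 51.3%. CACGTG made up 2.78% of the pairs and 7.57% of all E-boxes at summits. No PTF1 binding was measured in these 2 libraries.

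Regions with a narrow pair carried the NR5A motif less often than the rest. It was present in 12.4% (9.91 to 15.2%) of the 630 regions, 78 in number, against 21.6% (21.1 to 22.02%) of the 31343 regions without a pair (Fisher's exact test over regions, two-sided p = 4.3e-09). For pairs in the opposite orientation the share with the NR5A motif was 17.8% (13.01 to 23.4%) of 225 regions, against 21.4% of the other regions, and this difference did not pass the same exact test (p = 0.22). The shares of both orientations have overlapping intervals and were not tested against each other. A lower share particular to the PTF1 orientation is therefore not shown. The pairs were not limited to weak regions: the median fold was 8.93 with a pair and 8.30 without, and the share with a narrow pair was 3.75% (3.12 to 4.47%) in the strongest decile and 0.782% (0.507 to 1.15%) in the weakest (Fisher's exact test, p = 2.1e-16). The opposite orientation gave 1.03% and 0.532% in the same deciles. The counts at 6 bp exceeded those of the opposite orientation under each of the 7 other ways of calling regions that were tried.

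**Figure D3:**
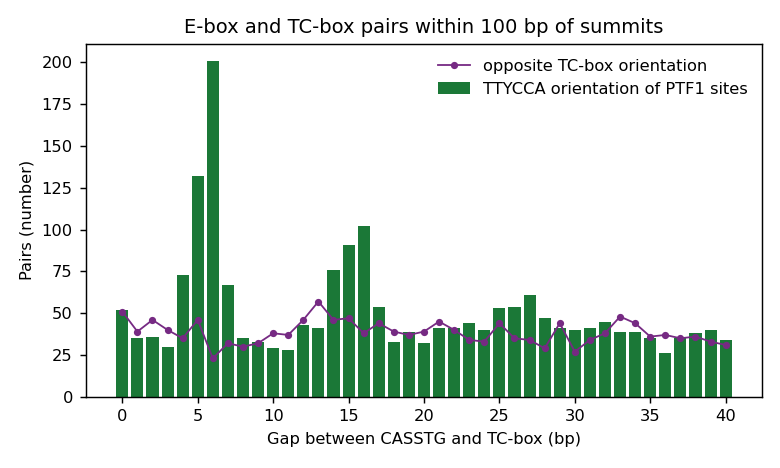
Number of E-box and TC-box pairs within 100 bp of the summits (y axis) against the gap between both boxes in bp (x axis); bars show the orientation of PTF1 sites and the line the opposite TC-box orientation. The bars stand out around 6 bp (201 pairs) and 16 bp (102 pairs), where the opposite orientation has 23 and 38. Gaps beside these are raised too, with 132 pairs at 5 bp, 91 at 15 bp and 76 at 14 bp.

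**Figure D4:**
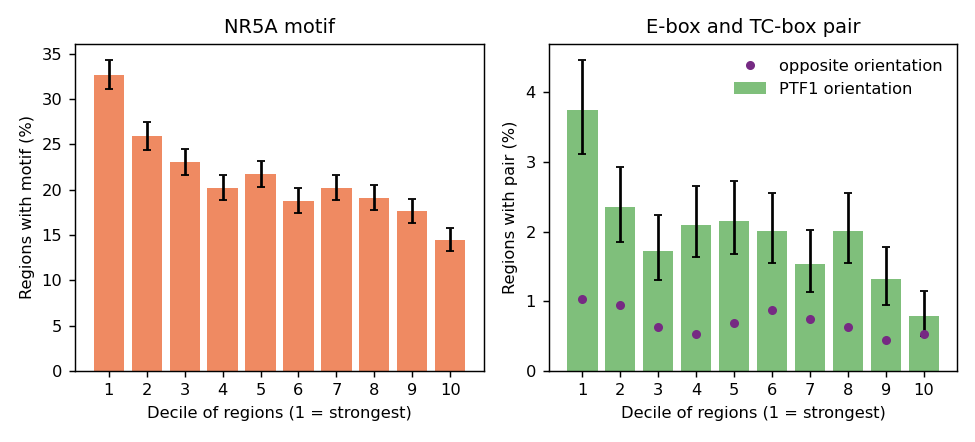
Percent of regions with the NR5A motif (left) and with an E-box and TC-box pair at a gap of 5 to 7 or 15 to 17 bp (right) in deciles of the 31973 regions, ordered from the strongest (1) to the weakest (10) by p; error bars are exact 95% intervals and points the opposite orientation. The motif falls from 32.7% to 14.5% and the pair from 3.75% to 0.782%.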

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

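The limit on NR5A motifs among Y regions was a test chosen after the excess was seen; the mismatch test was set before its result was known.

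Reads outside the chromosomes compared drew attention because they carried signal in data that no comparison used. The input file held 12719 reads on 8 unplaced contigs, and the LRH-1 file named no such contig. The mitochondrial genome held 8918 LRH-1 reads, 0.0724% (0.0709 to 0.0739%) of the library, and 12704 input reads, 0.122% (0.120 to 0.124%).

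Chromosome Y held 6.73 times (6.35 to 7.14) as many LRH-1 reads as scaled input, where every other chromosome lay between 0.972 and 1.06, and 70 regions were called there. LRH-1 binding at the Y sequence itself was argued against by the motif: 0 of the 70 regions held YCAAGGYCA, which allows up to 4.29%, while 21.4% of autosomal regions held it, although only 50.7% of 9-base words at the Y summits were known. The search read the recorded Y bases, so it cannot speak to binding at near copies elsewhere. The limit treats the 70 regions as independent, although 6021 of the 9807 LRH-1 reads in the bins of excess fell in 1 bin of 200 kb. A candidate explanation is technical. If the LRH-1 reads were aligned without the unplaced contigs, reads from near copies on those contigs could be placed on Y with mismatches. In the 5 bins of 200 kb where LRH-1 reads reached 3 times scaled input, 78.4% (77.6 to 79.3%) of LRH-1 reads had a mismatch, against 26.8% (24.4 to 29.3%) in the other Y bins, among them 1 bin at 2.96 times, and 9.95% on the autosomes, which is what that explanation needs.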

How the results depend on the processing

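The restriction to regions off Y with input nearby and the restriction to regions with every 9-base word known were chosen after the results were seen; the other alternatives were fixed before. No paired analysis was possible because there was 1 library per arm, and leaving out a replicate does not apply. The planned shares near transcription start sites and gene lists were not run under any setting, because gene positions on mm9 were not used here.

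Of the alternative values, 8 stayed within the main value's interval (for region counts, within 1.5 times) and 26 moved beyond it. The intervals are narrow because they cover counting error only. Region counts moved by over 1.5 times under 2 settings: 17877 at 8 times the expected reads and 81733 with no input in the expected count. The cause of these shifts was not tested. The share of LRH-1 reads in regions was 15.2% with all reads kept, 11.9% at the stricter p, 8.85% at 8 times, 14.03% with background scaling, 22.1% with no input, 11.5% with 50% of the reads and 13.04% off Y with input nearby.

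The share of regions with the NR5A motif was 18.97% with all reads kept, 22.9% at the stricter p, 24.1% at 8 times, 20.6% with background scaling, 22.7% with 50% of the reads, 34.2% for the core, 18.5% within 50 bp and 22.7% where every 9-base word was known. The share with an E-box and TC-box pair was 3.86%, 5.05% and 4.89% under the first 3 of these, 5.08% with 50% of the reads, 2.64% within 50 bp, 1.97% with narrow gaps and 5.73% where every 9-base word was known. Neither the NR5A share nor the pair share was computed with no input in the expected count, the setting that gave the most regions. The ratio at YCAAGGYCA was 3.58 with all reads kept and 3.77 within 50 bp. Pairs at 6 bp ran from 126 to 280 and those of the opposite orientation from 16 to 47 over the settings. Depth limits the list of regions: 10% of the LRH-1 reads gave 5349 regions and 25% gave 12782.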

Other observations

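The list of other motifs, the E-box and TC-box orientation test and the B1 contexts were chosen after the region sequences were seen; the tests of spacer identity, of gaps in input reads and of the B1 copies were set before their results were known.

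Sites of several other transcription factors lay at LRH-1 summits more densely than in the flanks. The palindrome bound by NFI factors, TTGGCNNNNNGCCAA, was 67.1 times (44.8 to 105) denser within 50 bp of summits, in 288 regions, and its single arm TTGGCA 3.48 times (3.38 to 3.59). The GATA site WGATAAG was 3.08 times (2.92 to 3.24) denser, in 10.6% of regions, and the forkhead site TGTTTRC 2.41 times (2.31 to 2.52), in 13.4%. The E-box CAGCTG was 2.09 times denser (2.02 to 2.17) and CACCTG 1.68 times (1.63 to 1.74), while the E-boxes CATCTG and CATATG stood at 1.01 (0.965 to 1.05) and 0.783 (0.712 to 0.859). An HNF4 site was 2.67 times denser (2.20 to 3.23) and a CTCF site 4.96 times (4.07 to 6.03). The AP-1 site stood at 1.16 (1.07 to 1.26), the ETS site at 0.917 (0.673 to 1.23), the SP1/KLF site at 0.658 (0.536 to 0.800), the TATA sequence at 0.593 (0.524 to 0.669) and a homeobox site CTAATTA at 0.678 (0.571 to 0.799).

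Of these, 3 were tested between regions with and without the NR5A motif, and all 3 were more frequent where it was missing (Fisher's exact test over regions, two-sided p = 3.7e-21 for the NFI palindrome, 1.6e-13 for GATA and 3.6e-17 for CAGCTG, unadjusted for the 3 tests). NFI palindromes were present in 0.102% (0.0412 to 0.211%) of regions with the NR5A motif and 1.12% (0.992 to 1.26%) of the others. GATA sites were present in 8.19% (7.55 to 8.87%) and 11.2% (10.8 to 11.6%), and CAGCTG in 15.8% (14.9 to 16.7%) and 20.2% (19.7 to 20.7%). CATCTG, not denser at summits, was also rarer with the NR5A motif, at 13.1% (12.3 to 13.96%) against 15.2% (14.8 to 15.7%). CATATG and the AP-1 site were not rarer, at 3.38% against 3.17% and 4.18% against 4.17%. A lower share is therefore not particular to sites enriched at summits. How much of the GATA and CAGCTG differences is particular to these sites was not tested. In the 21026 regions without the core AAGGYCA, which were 65.8% of all regions and 50.5% of the strongest decile, the NFI palindrome was 97.3 times denser than in the flanks (58.7 to 173), the GATA site 3.26 times (3.07 to 3.46) and CAGCTG 2.29 times (2.20 to 2.39). Sites with 1 base changed from YCAAGGYCA were 3.34 times denser there (3.24 to 3.44). Of regions judged for base composition, 2.55% (2.36 to 2.75%) were CpG-rich, and these had a median fold of 5.84 against 8.76 for the rest.

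The E-box and TC-box gaps of 6 and 16 bp were set against 3 explanations. If most sites were copies of 1 repeated element, they would share the bases between both boxes, but spacers of different sites matched at 25.8% of bases on average, the level of unrelated sequence. This mean cannot exclude a minority of copies: 186 of the 201 spacers at 6 bp were distinct, as were all 101 compared at 16 bp. A preference of the mouse genome for these gaps would show in input reads outside regions, where the pair was 1.04 times as frequent at 6 bp as at the median gap. At summits, in counts of pairs, the PTF1 orientation had 5.15 times as many at 6 bp as at the median of gaps outside its clusters, and the opposite orientation 0.605 times its median over all gaps of 0 to 40 bp. These denominators differ from that of the input reads. A hypothesis that stays open is that part of the LRH-1 regions hold sites of a PTF1-type complex, with or without contact of LRH-1 to DNA there, which these libraries do not test.

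Some NR5A motifs lay in a sequence context of the B1 repeat, a short interspersed element, where loss of a CpG in the repeat leaves the motif. The context GTTCAAGGYCAGCC was 8.82 times (7.55 to 10.3) denser at summits than in flanks and was found in 437 regions, 6.39% of those with the motif. If reads were misplaced among copies of the repeat, copies with the CpG intact (GTTCGAGGYCAGCC) would be as enriched, but their LRH-1 over input ratio was 1.07 (0.925 to 1.24), against 3.19 (3.03 to 3.37) around the 1716 copies with the motif. NR5A motifs elsewhere had 3.18 (3.15 to 3.22), and copies decayed on the other strand (GTTTGAGGYCAGCC) 1.26 (1.16 to 1.36). A hypothesis is that LRH-1 may bind B1 copies that carry the motif about as well as other copies of it, although the call of a B1 context rests on 14 bases, of which only 39.5% of copies continued with the TGG of the repeat against 1.56% by chance.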
